A study of Homo sapiens with 17 samples.

How the data were processed

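Small RNA was sequenced from K562, a human erythroleukemia line, carrying a doxycycline (Dox) inducible short hairpin RNA against Drosha, the nuclease that opens primary microRNA transcripts. Per the labels' protocols, cells were kept with 1 µg/mL Dox or with water in parallel for 3, 13 or 31 d, as independent biological replicates, and libraries were size-selected on a gel to 20 to 40 nt. The series held 17 libraries, of which 8 were Dox, 8 were water and 1 was untreated. There were 2 Dox and water pairs at 3 d, 3 at 13 d and 3 at 31 d. The labels name 1 table for the Dox library together with the water library of the same day and number, which gave 8 tables. The untreated library was not analysed here.

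Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.9 to the human build hg19 (GRCh37). Each table lists distinct alignments by chromosome, start, end and strand. The value used was the deposited ratio of 1 library to the other, as the authors computed it: in every row it equals the quotient of a pair of length- and library-scaled values in the same table, within floating-point error. The tables have no header, and neither they nor the labels state which library is the numerator. Ratios are therefore given as numerator over denominator, with no Dox direction attached, and that all 8 tables run the same way is an assumption. The 4 other value columns of each table, 32 in all, carry no library name. They were looked at only to learn what the ratio is and enter no result, so no depth per library and no counting interval is given. The ratio was 0 where the numerator had no reads, and how reads with several possible positions were placed is not given in the sources used here.

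The reference in hand is of build GRCh38, and coordinates were not converted. No gene or microRNA name was attached to any position: the microRNA lists, the named microRNAs, the Drosha locus and the cell type markers fixed before the data were examined could not be matched and have no value here. Positions are 1-based on hg19.

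The tests planned for counts did not apply to ratios. As fixed beforehand for that case, the log2 ratio of each pair was tested against 0 with limma 3.58.1 in R 4.3.3 (robust empirical Bayes), with 1 mean per day over all 8 tables and Benjamini-Hochberg adjustment at 0.05. Each day was tested on alignments with a ratio above 0 in every table of that day, since 0 has no logarithm, and contrasts between days on those present for both days. Limma estimated 1 common variance for all alignments, so that the standard error was 1.32 at 3 d and 1.08 at 13 d and 31 d. The degrees of freedom were 574300, pooled over alignments that can overlap. The standard error and p of an alignment thus do not measure the spread of its own pairs, and its p may be too small. Tested on simulated data with the spread of the real tables and 200 changed alignments, limma at 3, 13 and 31 d recovered 38%, 58% and 56% of 50 changes of log2 size 8, at most 2% of those of size 4 and 0% of smaller ones, and called 0% of unchanged alignments. Noise was drawn independently for each alignment, without the shifts, length trends or overlaps of the real tables, so the 0% is no rate of false calls for them. In the real tables the smallest size of a called log2 ratio was 4.11 at 3 d, 3.003 at 13 d and 3.62 at 31 d, so the simulated shares do not carry over. The adjustment is less strict where more alignments change, and the variances of the simulated and real fits may differ, which was not compared. Changes of single alignments below those sizes could not be called.

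Alignments were also grouped, by a definition made after the data were seen. A stack was at least 3 alignments of 20 to 24 nt with 1 common 5′ end and a ratio above 0 in all 8 tables; stacks up to 8 nt apart were merged. Neighbouring stacks on 1 strand with 5′ ends 30 to 48 nt apart formed a two-arm locus with a 5p side and a 3p side, and all others were single stacks. The value of a stack was the median log2 ratio of its alignments per table, tested with the same limma model. Its standard errors draw on the variance of all stacks and so need not show the spread of the pairs of 1 stack. Camera compared two-arm sides with other stacks. Medians per table were tested by exact sign-flip permutation, two-sided; 37 such tests were computed over 5 measures and over fragments flanking the loci, and their adjusted values cover all 37. Before the data were examined, the alignments to be named were fixed as the 10 largest rises and 10 largest falls per day among those past the threshold with 1 direction in every pair; no level minimum could be set on ratios. Stacks and loci are named by values seen first.

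Alternatives planned beforehand were centring each table on its median, fitting each day alone and leaving out each pair; the planned sums per hairpin could not be made. Those added after seeing the data were stacks in place of alignments, centring by length, a minimum of 18 nt, alignments above 0 in all 8 tables, the replicate number as a block across days, leaving out the 13 d replicate 3 and 31 d replicate 2 tables, and two-arm spacings of 35 to 42 nt. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.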

Results

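The data were 8 tables of deposited ratios, each comparing a Dox with a water library of K562 cells carrying an inducible hairpin against Drosha. The question behind the design is which small RNAs depend on Drosha, and how this changes from 3 to 13 and 31 d of induction. Together the authors' deposited tables listed 14415896 distinct alignments of 10 to 42 nt, and 871027 to 3428554 in a single table. The ratio was 0 for 73.2% to 93.1% of a table's alignments. A ratio above 0 in all 8 tables was found for 26250 alignments. Across these, log2 ratios of tables of the same day correlated at Pearson r = 0.273 to 0.678, those of 13 d with 31 d at 0.229 to 0.668, and those of 3 d with later days at -0.44 to 0.280; alignments are not independent replicates. No pair of tables shared identical ratios. The median log2 ratio of the 26250 alignments was 0.59 and 1.60 at 3 d, 0.83, -0.16 and 0.03 at 13 d, and 0.26, 0.95 and -0.59 at 31 d, so that tables were shifted against each other, and splits after centring each table are given beside the main ones. Which library is the numerator is not stated; if it is the Dox library, a ratio below 1 means less RNA with Dox.

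The highest ratios at all 3 times came from 1 short site on chromosome 5, from 31511235 to 31511265, with stacks of 20 to 24 nt on both strands. The plus-strand stack had a mean log2 ratio of 9.47 ± 0.70 (SE, n = 2 pairs) at 3 d, 9.17 ± 0.57 (n = 3) at 13 d and 7.25 ± 0.57 (n = 3) at 31 d. The minus-strand stack had 8.81 ± 0.69, 7.85 ± 0.56 and 5.24 ± 0.56. These SE draw on the variance of all stacks and do not show the spread of the pairs. At 13 d the 3 pairs had 9.10, 10.59 and 7.80 on the plus strand and 7.87, 8.06 and 7.62 on the minus strand. Both were above 0 in 8 of 8 tables and above every other stack of the same table (limma adjusted p of 6.19e-15 or lower). In the authors' deposited tables, the 24 nt alignment from 31511242 to 31511265 on the plus strand had ratios from 194 at 31 d, replicate 1, to 10312 at 3 d, replicate 3. Alignments at this site made up 9 of the 10 largest rises at 3 d and 10 of 10 at both 13 d and 31 d. From 3 d to 31 d the ratio fell by 2.23 on the plus and by 3.57 on the minus strand, on the log2 scale, past the threshold as deposited. After centring the differences were -1.33 (limma adjusted p = 0.274) and -2.68 (limma adjusted p = 0.0217), so that only the minus strand passed.

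**Figure D1:**
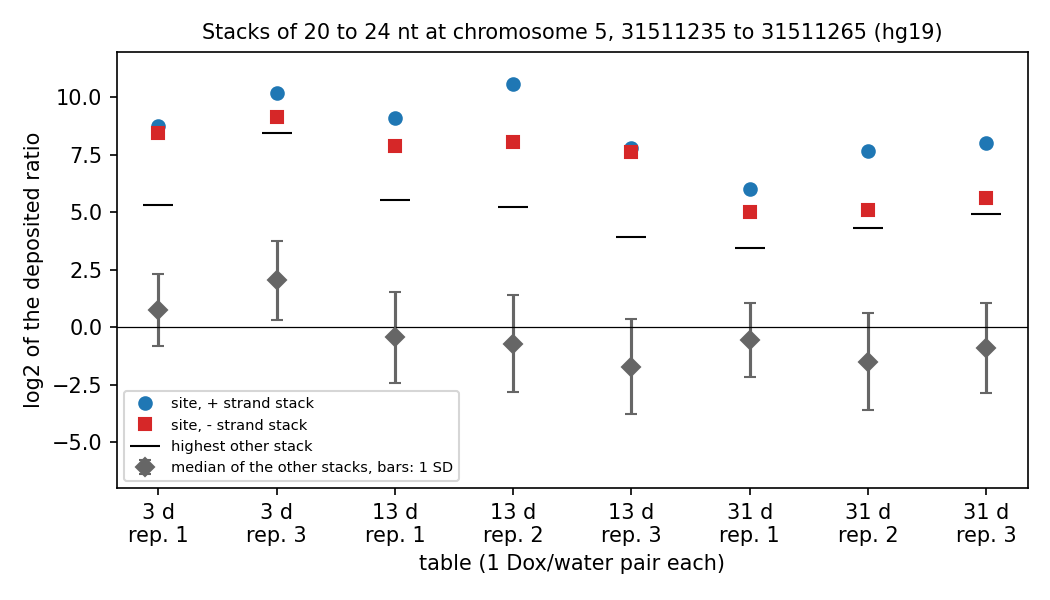
Log2 of the deposited ratio (y axis) in each of the 8 tables (x axis) for the plus-strand (circles) and minus-strand (squares) stacks of the chromosome 5 site, with the median of the other stacks (diamonds, bars 1 SD over stacks) and the highest other stack (dashes). Both site stacks lie above the highest other stack in every table.

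At 3 d most alignments that passed the threshold had a ratio above 1. Outside the chromosome 5 site, the largest rise was at chromosome 5, 78176852 to 78176871, plus strand. Its log2 ratio was 9.50 ± 1.32 (SE, n = 2 pairs, limma adjusted p = 6.46e-09), and its pairs had 10.72 and 8.29. All alignments at 3 d share this SE, which does not show the spread of the pairs. The 10 largest falls ranged from -6.59 to -5.98; the lowest were chromosome 8, 68497723 to 68497748, at -6.59, and chromosome 14, 20811478 to 20811511, at -6.57, both on the minus strand. The pairs of the former had -8.16 and -5.02, and those of the latter -9.84 and -3.30; without replicate 1, 7 of the 10, these 2 among them, did not pass. Of 111976 alignments tested, 4129 passed by limma, 88.3% of them higher, and after centring 4801, 91.1% of them higher. The test left out 429039 of the 541015 alignments listed in both 3 d tables, for a ratio of 0 in at least 1 of them (187108 in both), and alignments without denominator reads are not listed, so the split covers only alignments with reads in both libraries of every pair. This direction rested on replicate 3: without it 680 were higher and 3210 lower, and without replicate 1, 2738 and 12.

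At 13 d alignments moved both ways. The 10 largest falls were short, 16 to 20 nt, with log2 ratios of -8.47 to -7.31; the largest was at chromosome 14, 99520789 to 99520804, minus strand, at -8.47 ± 1.08 (SE, n = 3 pairs, limma adjusted p = 1.36e-11), followed by chromosome 12, 20636667 to 20636686, plus strand, at -8.33. Sequences this short can match many positions in the genome. Several falls had like values in the 3 pairs. The 16 nt ones at chromosome 14, 99520789, and chromosome 3, 119666365, had -7.65, -10.81 and -6.94, and -7.69, -10.83 and -6.44. The 20 nt ones at chromosome 12, 20636667, and chromosome 2, 162628751, had -6.76, -10.06 and -8.17, and -6.41, -10.11 and -7.94. Such falls may be copies of 1 sequence, so the 10 need not be separate sites, which was not tested. Of 69772 alignments tested, 4257 were higher and 3130 lower by limma, or 4946 and 5075 after centring. Among the 35462 of 18 nt or longer, tested alone, 2087 were higher and 2968 lower, so the uncentred split turned. Left out of the main test were 89949 of 159721 listed in all 13 d tables, for a ratio of 0 in at least 1. Of these, 23456 had 0 in every table. Without replicate 2 the count of 7387 fell to 588, without replicate 3 to 776 (236 higher and 540 lower), without replicate 1 to 4386 and, through the common variance, without 31 d replicate 1 to 4382.

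At 31 d most alignments past the threshold had a ratio below 1. The 10 largest falls, 16 to 19 nt long, had log2 ratios of -8.30 to -7.57; the largest were at chromosome X, 38582042 to 38582059, minus strand, at -8.30 ± 1.08 (SE, n = 3 pairs, limma adjusted p = 1.20e-10), and at chromosome 8, 121224571 to 121224586, plus strand, at -8.26. Of 123762 alignments tested, 348 were higher and 1565 lower by limma, or 218 and 2367 after centring; 152987 of 276749 listed in all 31 d tables were left out for a ratio of 0 in at least 1, and 36466 of these had 0 in every table. Without replicate 3 the count of 1913 fell to 171, without replicate 1 to 507 and without replicate 2 to 872.

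The falls at 13 d and 31 d shared alignments. Among 46562 alignments tested at both times, 435 were lower at both, where independent lists would share 40.9, and 153 were higher at both, where independent lists would share 16.6. Overlapping alignments and possible copies of 1 sequence were counted separately, so the lists may hold fewer independent members. Of those called in 1 direction at 13 d, 0 were called in the other at 31 d. With 3 d the overlap was mixed. Of alignments tested at 3 d and 13 d, 792 were higher at both (157.8 expected) and 32 lower at both (9.43 expected). Another 65 were higher at 3 d and lower at 13 d. Of those tested at 3 d and 31 d, 26 were higher at both (10.0 expected) and 0 lower at both (4.19 expected). Another 39 were higher at 3 d and lower at 31 d. The difference between 31 d and 13 d passed the threshold for 0 alignments by limma, with 1920 at an unadjusted p below 0.05. Against 3 d, 13 d was higher for 92 and lower for 3813 of 34539 alignments, and 31 d higher for 502 and lower for 2619 of 41756. Without 3 d replicate 3 the latter split turned to 1770 higher and 896 lower, and the former was 271 and 1272. The 13 d count of 3905 fell to 2153 without 3 d replicate 1 and to 1764 without 13 d replicate 2, and the 31 d count of 3121 fell to 1702 without 3 d replicate 1 and to 632 without 31 d replicate 1.

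MicroRNAs can come from both sides of a hairpin, so stacks of 20 to 24 nt were searched for such pairs by position alone. The 26250 alignments held 523 stacks, and 62 pairs of neighbouring stacks had 5′ ends 30 to 48 nt apart, with a median of 38 nt. Equally wide windows of 9 to 27 nt, 49 to 67 nt and 68 to 86 nt held 3, 9 and 2 pairs. These 62 two-arm loci have the spacing of hairpin-derived microRNAs, though no name or sequence was matched to them. Other RNAs with this spacing were not told apart from microRNAs, so values of the class need not be those of microRNAs. The loci on chromosome 8 from 41517962 to 41518025, plus strand, and from 41517960 to 41518023, minus strand, overlap and may hold the same reads.

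**Figure D2:**
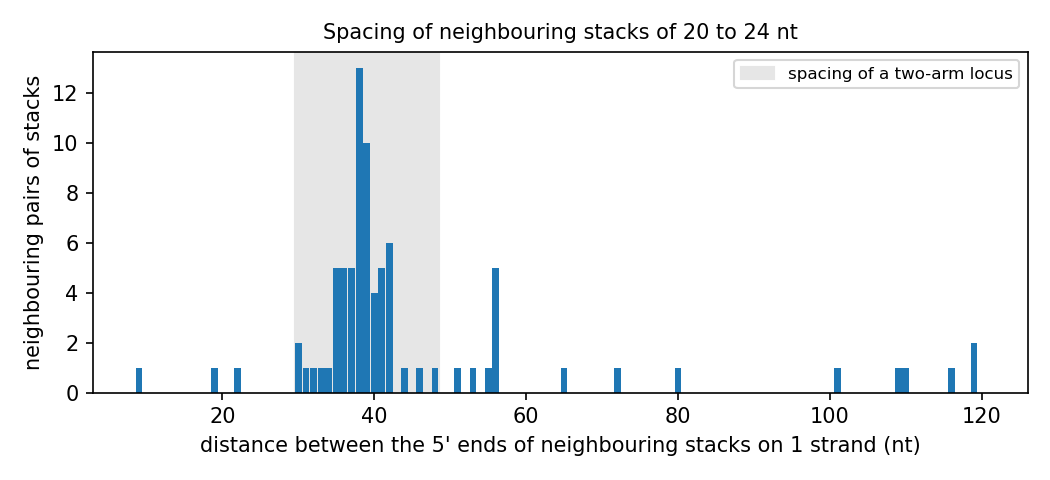
Number of neighbouring pairs of 20 to 24 nt stacks on 1 strand (y axis) by the distance between their 5′ ends in nt (x axis, up to 120 nt); grey marks the spacing of 30 to 48 nt that defines a two-arm locus. Most pairs lie within the grey band.

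Among called sides of two-arm loci, most were lower at 13 d and 31 d, and at 31 d this lead shrank relative to alignments of like length. By limma, 67 of the sides of these 62 loci were lower and 13 higher at 13 d, and 58 were lower and 11 higher at 31 d. After centring on all alignments the splits were 68 and 6 at 13 d, and 58 and 6 at 31 d. Relative to alignments of 20 to 24 nt they were 63 lower and 22 higher at 13 d, and 41 lower and 30 higher at 31 d, where the median was -0.16. At 3 d, 66 sides were higher and 3 lower as deposited, but 1 higher and 4 lower after centring, and without replicate 3 the limma count was 0, with 21 at an unadjusted p below 0.05. The 13 d and 31 d tables gave two-arm medians of -1.14, -0.99 and -2.10, and of -0.90, -1.32 and -0.86, below 0 in 6 of 6 (exact sign-flip p = 0.0312, the smallest possible; adjusted p = 0.361 over 37 tests).

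Fewer than 50% of single stacks were called lower at the later times, and so were fewer than 50% of two-arm sides at 31 d. No test separated two-arm sides from single stacks at these times. At 13 d 164 of 399 single stacks were lower and 60 higher, and at 31 d 171 and 39. Relative to alignments of 20 to 24 nt 153 were lower and 113 higher at 13 d (median -0.0727) and 134 of 241 called were lower at 31 d (median -0.0389). The two-arm median minus that of single stacks averaged -0.38 ± 0.44 (SD, n = 6 tables) over the later times (exact sign-flip p = 0.125, adjusted p = 0.463). It was -0.67 ± 0.33 (SD, n = 3) at 13 d, below 0 in 3 of 3 tables, and -0.09 ± 0.38 (SD, n = 3) at 31 d, below 0 in 1 of 3 (exact sign-flip p = 0.25, the smallest possible, and 1; adjusted p = 0.532 and 1). Camera with a preset correlation of 0.01 gave adjusted p = 0.00964 at 3 d, toward higher ratios, and 0.163 and 0.909 at 13 d and 31 d; with an estimated correlation the adjusted p was 0.982 at every time.

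Within the two-arm class, loci differed widely, while at 13 d and 31 d their 2 sides had similar values. Both sides were lower at 30 of 62 loci at 13 d and 25 at 31 d, at 22 loci at both times. By the mean over both sides and both times, the largest of these falls was on chromosome 16, from 15005094 to 15005159, with log2 ratios of -4.21 ± 0.57 (SE, n = 3 pairs) and -4.54 ± 0.57 for the 5p and 3p sides at 13 d and -4.39 ± 0.57 and -3.98 ± 0.57 at 31 d. The next were the locus on chromosome 16 from 14403157 to 14403219, with -4.85 and -3.28 at 13 d, and that on chromosome 7 from 99691192 to 99691253, minus strand, with -4.33 and -3.16. All of these sides passed the threshold at both times (highest limma adjusted p = 6.23e-07). Both sides were higher at 3 loci at both times. These were on chromosome 1 from 175937536 to 175937596 with 3.75 ± 0.57 and 3.47 ± 0.58 at 13 d, on chromosome 15 from 83424760 to 83424822 with 3.05 and 2.83, and on chromosome 1 from 220373890 to 220373951 with 2.37 and 2.40. After centring, 1 side of the last was no longer past the threshold at 31 d. At neither 13 d nor 31 d did any locus have sides called in opposite directions (0 of 62). At 3 d 2 loci did and 23 had only 1 side called as deposited, against 0 and 5 after centring, with neither side called at 57. Across the 62 loci, the 5p and 3p values correlated at r = 0.918 (Spearman's rho = 0.917) at 13 d and 0.942 (rho = 0.942) at 31 d, each with a permutation p of 1e-05, the smallest 100000 permutations can give, and an adjusted p of 1.5e-05 over 6 tests. At 3 d r was 0.358 (permutation p = 0.00467, adjusted p = 0.0056; rho = 0.288, permutation p = 0.023), and by table it was 0.0474 in replicate 1 and 0.565 in replicate 3. Loci are not independent replicates.

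**Figure D3:**
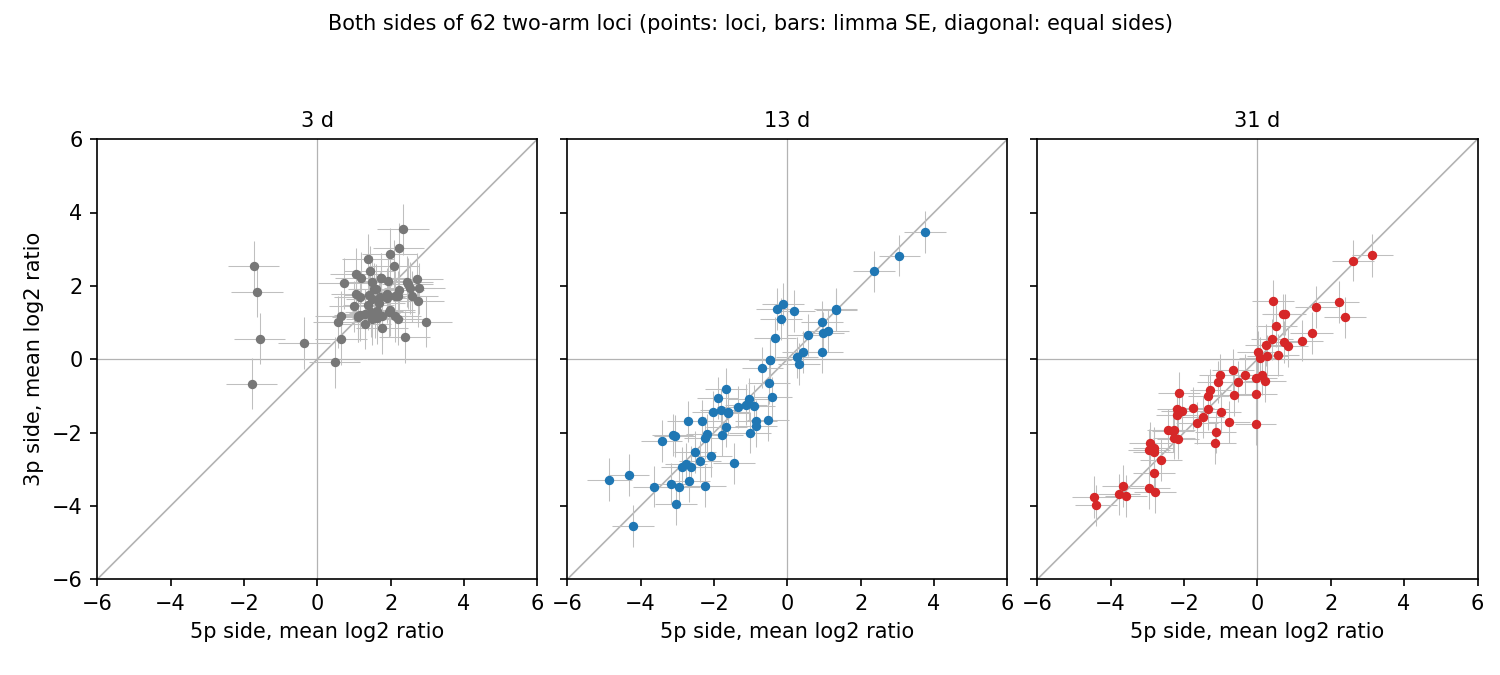
Mean log2 ratio of the 3p side (y axis) against that of the 5p side (x axis) for 62 two-arm loci at 3, 13 and 31 d. Bars are limma standard errors, which draw on all stacks and do not show the spread of the pairs, and the diagonal marks equal sides. Points follow the diagonal at 13 d (r = 0.918) and 31 d (r = 0.942) and scatter more widely around it at 3 d (r = 0.358).

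One stretch of chromosome 13 held several loci. Between 92002871 and 92003384 on chromosome 13 lay 3 two-arm loci on the plus strand. The middle one, from 92003010 to 92003074, had log2 ratios of -3.62 ± 0.58 and -3.47 ± 0.57 (SE, n = 3 pairs) at 13 d and -3.66 and -3.45 at 31 d, past the threshold for both sides. The first, from 92002871 to 92002932, had -0.91 and -1.27 at 13 d, and the last, from 92003326 to 92003384, had -0.85 and -1.83; of these only the 3p sides passed at 13 d (limma adjusted p = 0.0478 and 0.0041). At 31 d the first had -0.78 and -1.71, with its 3p side past the threshold (limma adjusted p = 0.00749), and the last had -0.64 and -0.97, with neither side past it. The outer loci leaned on 13 d replicate 3. Their 5p sides had -0.41, -0.15 and -2.16, and -0.67, 0.62 and -2.51, in the 3 tables of 13 d. Their 3p sides had -0.98, -0.79 and -2.04, and -1.50, -1.15 and -2.84, below 0 in each of these tables. Without 13 d replicate 3 none of their sides passed at 13 d. Whether the loci differ from each other was not tested.

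Among the 397 single stacks outside the chromosome 5 site, 36.3% were lower and 8.06% higher at both 13 d and 31 d. By the mean over both times, the largest falls were on chromosome 8 from 144815257 to 144815280, at -5.17 ± 0.57 (SE, n = 3 pairs) and -5.60 ± 0.57, on chromosome 20 from 61918170 to 61918193, at -4.84 and -5.21, and on chromosome 2 from 12339264 to 12339287, at -5.75 and -3.93. The largest rises by that mean were on chromosome X from 154003339 to 154003362, at 4.69 ± 0.57 and 3.24 ± 0.57, on chromosome 6 from 30552109 to 30552132, at 4.30 and 3.42, and on chromosome 11 from 8705774 to 8705796, at 3.66 and 4.05. All passed the limma threshold at both times (highest adjusted p = 3.56e-07).

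Ratios depended on alignment length, most strongly in a pair of tables. In 13 d replicate 3 and 31 d replicate 2 the median log2 ratio of alignments above 0 in all tables was 1.78 and 2.51 at 10 to 17 nt, and -1.65 and -3.97 at 25 to 30 nt. In the other 6 tables, in the order of time and replicate, the medians at 10 to 17 nt were 0.30, 1.76, 1.07, -0.26, 0.53 and -0.70, and those at 25 to 30 nt were 0.45, 0.13, 0.81, 0.72, 0.23 and 0.30, so that 3 d replicate 3, 13 d replicate 1 and 31 d replicate 1 were also lower at the longer lengths. Without the pair of tables, 43 two-arm sides were lower and 14 higher at 13 d, and 45 and 8 at 31 d.

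**Figure D4:**
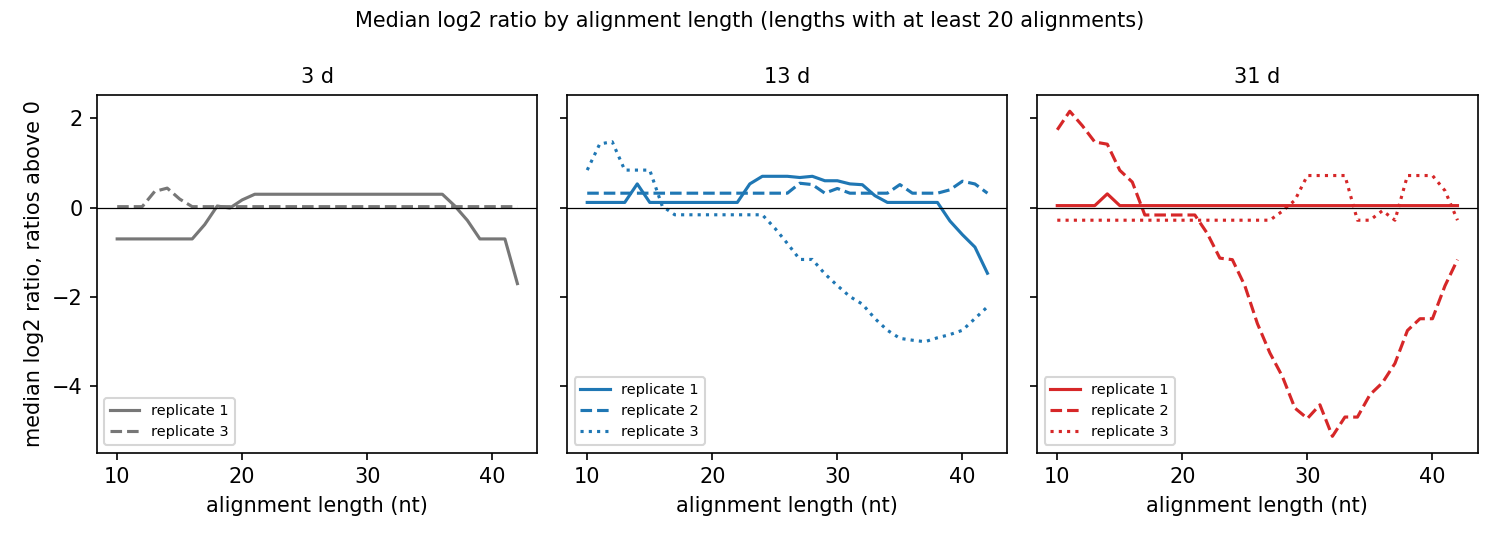
Median log2 ratio of alignments with a ratio above 0 (y axis) by alignment length in nt (x axis) for each table, in panels for 3, 13 and 31 d; lines are replicates, and only lengths with at least 20 alignments are drawn. The 13 d replicate 3 and 31 d replicate 2 lines drop with length and rise in part at the longest lengths. The others stay near 0 over most lengths, often at exactly the same median, since many alignments of a table share the same ratio.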

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

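The tests of explanations and of other sign patterns in this part were chosen after the results were seen. The test of the difference between times was planned, but stacks and two-arm loci were defined after the data were seen. Values below are log2 differences from 3 d that passed the limma threshold in that test, for sites named above. Most of these sites were named for extreme values at the times compared. That choice favours large differences, so how many passed is no independent evidence of a change between times.

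The difference from 3 d was past the threshold for 3905 alignments and 91 two-arm sides at 13 d, and for 3121 alignments and 86 sides at 31 d. Among named alignments, those at the chromosome 5 site that differed were 31511240 to 31511260 and 31511240 to 31511261, minus strand, at -5.44 and -5.47 at 31 d. Chromosome 5, 78176852 to 78176871, differed by -8.97 at 13 d and -8.62 at 31 d. The 3 d falls that differed were chromosome 14, 20811478 to 20811511, by 6.26 at 13 d, 20811478 to 20811509 by 5.97 at 31 d and 20811277 to 20811307 by 4.77 at 13 d, and chromosome 5, 99444713 to 99444730, by 7.13 at 31 d. Without 3 d replicate 1 these differences were 2.99, 3.09, 5.15 and 3.81, and none passed. Of the 13 d falls, chromosome 12, 20636667, differed by -10.20 at 13 d and -5.37 at 31 d, and chromosome 5, 175912038, by -8.84 and -7.41. Also past the threshold at 13 d, chromosome 3, 119666365, differed by -9.28, chromosome 2, 162628751 and 67363666, by -9.07 and -9.10, and chromosome X, 112615616, 143766313 and 73438284, by -9.08, -8.60 and -7.21. Some of these positions may be copies of 1 sequence, as given above. Of the 31 d falls, chromosome X, 38582042, differed by -10.69 and chromosome 14, 56257644, by -9.11 at 31 d, chromosome 8, 14563770, by -6.23 at 13 d and -9.11 at 31 d, and chromosome 9, 135711038, by -7.83 and -9.98.

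Named stacks differed from 3 d as follows, at 13 d and then 31 d. On chromosome 16 the 5p and 3p sides at 14403157 and 14403197 differed by -6.83 and -6.15, then -6.42 and -6.62, and those at 15005094 and 15005138 by -6.33 and -5.71, then -6.52 and -5.15. On chromosome 7 those at 99691253 and 99691215 differed by -6.79 and -5.22, then -6.24 and -5.74. On chromosome 13 the values were -2.37 and -2.56, then -2.24 and -3.004, for the first locus, -4.91 and -4.70, then -4.94 and -4.68, for the middle one, and -2.75 and -3.61, then -2.53 and -2.75, for the last. The single stacks on chromosome 8, 144815280, differed by -7.29 and -7.73, chromosome 20, 61918170, by -5.03 and -5.41, chromosome 2, 12339264, by -7.15 and -5.33, and chromosome 11, 8705774, by 4.63 and 5.02. Chromosome 6, 30552109, and chromosome X, 154003339, differed by 2.40 and 2.47 at 13 d. The chromosome 5 stacks differed by -2.23 (plus) and -3.57 (minus) at 31 d. After centring, 28 of these 36 stack differences and 23 of the 24 alignment differences still passed. The others were the plus-strand chromosome 5 stack at 31 d (-1.33), both sides of the first chromosome 13 locus (-1.51 and -1.70, then -1.35 and -2.11), the 5p side of the last (-1.89, then -1.64), its 3p side at 31 d (-1.86) and chromosome 14, 20811478 to 20811509, at 31 d (5.52, limma adjusted p = 0.0554). With any 1 table left out, 25 of the 36 stack differences and 16 of the 24 alignment differences passed every time. The stacks that did not were all sides of the outer chromosome 13 loci, each lost without 3 d replicate 3, the plus-strand chromosome 5 stack, and those on chromosomes 6 and X.

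For the fall of two-arm sides from 3 d to later times, the count of sides called lower cannot decide on table scaling. At least 33 sides were still lower in either contrast after centring each table on all alignments or on those of 20 to 24 nt. Loci differ widely, however, so sides can be called in either direction under any centring. Centring on 20 to 24 nt took away much of the shift, with medians of -1.43 and -0.64 in place of -3.16 and -2.69. It left 18 and 17 sides higher at 13 d and 31 d. The tables with a length trend do not carry it alone, as 74 sides or more were lower without them, nor does either 3 d table, as 51 or more were lower without it. From 3 d to the later times the two-arm median relative to all alignments fell by 1.99 log2 (exact permutation p = 0.0357 over 28 splits of the tables, the smallest possible), relative to alignments of 20 to 24 nt it fell by 0.98 (exact permutation p = 0.0714) and relative to single stacks it fell by 0.73 (exact permutation p = 0.143), and over these 3 measures the lowest adjusted p was 0.107. Induction time cannot be told apart from culture or library batch, which the labels do not give.

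The length trend in 13 d replicate 3 and 31 d replicate 2 was compared within stacks, where alignments share a 5′ end. The median slope was -0.389 and -0.547 log2 per nt, below the lowest of the other 6 tables at -0.169, which argues against a shift between RNA classes as the whole cause. Recovery or trimming that favoured different lengths in the libraries of a pair may account for it, as a hypothesis; no other biological explanation was tested.

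The chromosome 5 site lay at least 3.13 SD above the median of the other stacks in every table, which a single factor per table cannot give, and after centring on 20 to 24 nt alignments its lowest mean was still 6.08 and past the threshold. An RNA made in 1 library of each pair was left open: all 16 values, from 2 strands and 8 tables, were above 0, but the site was picked for its high ratios, so this count decides nothing. Only alignments with denominator reads were listed, so both libraries of each pair held reads of the site. The sequence of the induced hairpin was not in the sources used here, so the site was not matched to it, and no direction was assigned to any table from it.

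As for chance, 3 pairs at 1 time make 4 sign patterns, too few for a share under 0.05. At 13 d the real pattern gave 7387 calls and the highest other 7, with 1 of 4 as large, and at 31 d 1913 and 0, with 1 of 4. The 10 splits of the 6 later pairs into 31 d and 13 d are also too few, with 0 calls for the real split and 117 for the highest other, so that 10 of 10 were as large. With the 6 later pairs together, 13125 of 46562 alignments were called and 2514 under the highest other of 32 sign patterns, with 1 of 32 as large. That is the smallest share these patterns can give. It was not adjusted for the other patterns and splits tried here, so chance was not excluded.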

How the results depend on the processing

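Counts of alignments moved by more than 1.5 times under several alternatives, and which of these were added after seeing the data is given in the description of the processing; the cause was not tested unless stated. Alternatives that need counts or levels per library (edgeR and DESeq2 scalings, count filters, pseudocounts, level minimums, microRNA shares and the Drosha locus) were not run, and a fit without pairs cannot be made from ratios. Leaving out 1 table at a time gave 2750 to 5767 alignments at 3 d, 588 to 10835 at 13 d, 171 to 2499 at 31 d, 1543 to 4704 for 13 d against 3 d, 632 to 3657 for 31 d against 3 d and 0 to 92 for 31 d against 13 d; for two-arm sides it gave 0 to 91, 63 to 82, 48 to 74, 57 to 93, 56 to 88 and 0 to 2. Where 3 d was left with 1 table, that table was assumed to vary like the others. Centring each table gave 7037 alignments for 31 d against 3 d, and 5 two-arm sides at 3 d and 53 for 31 d against 3 d. Centring by length gave 8893, 15468 and 3693 alignments at 3, 13 and 31 d, and 7726 and 10176 against 3 d at 13 and 31 d; on 20 to 24 nt it gave 11 two-arm sides at 3 d and 50 for 31 d against 3 d. Fits of 1 time alone gave 2520 at 3 d and 11319 at 13 d. Fewer alignments tested, those above 0 in all 8 tables, gave 4298 at 13 d and 972 at 31 d. Without 13 d replicate 3 and 31 d replicate 2 the counts were 6453, 2567 and 1055 at the 3 times and 5072 for 31 d against 3 d. At 18 nt or longer they were 1762 at 3 d and 3113 at 31 d. Stacks in place of alignments gave 261, 304 and 279 at the 3 times, and 335, 329 and 2 for the contrasts, out of 523. Ratios carry no depth, so precision per alignment is unknown. Many alignments shared exactly the same ratio, though. In 3 d replicate 3 the lower quartile and the median of log2 ratios above 0 were both 0.0195, and the upper quartile was 1.0195. Such steps are those of small whole read numbers, so many alignments may rest on few reads, which was not tested.

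The replicate block, with the replicate number shared between days, gave 2822 at 3 d, 1917 at 13 d, 291 at 31 d, and 1757 and 128 for 13 d and 31 d against 3 d, on the 26250 alignments above 0 in all 8 tables, where the counts without the block were 4622, 4298, 972, 4405 and 3380, and 26 two-arm sides at 3 d. The numbers were not shown to pair the tables, since deviations of same-numbered tables correlated at -0.52 to 0.309, above 0 in 4 of 7.

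Of the values of named alignments under alternatives, 819 kept direction and side of the threshold and 7 lost the threshold; of named stacks, 845 kept both, 76 lost and 6 gained it. Another 9 changed sign. At 3 d the stack at 61918170 on chromosome 20 became -0.90 after centring, -1.02 relative to 20 to 24 nt, -0.0892 with the block, and with either 3 d table left out it ranged from -0.36 to 0.75; those at 92002909 and 92003010 on chromosome 13 ranged from -0.0920 to 2.68 and from -0.58 to 3.15, and that at 15005138 on chromosome 16 became -0.0436 relative to 20 to 24 nt. At 31 d those at 92002872 and 92003326 became 0.0626 and 0.20 relative to 20 to 24 nt. None of these had passed the threshold. Two-arm minus single stacks over the later times was -0.48 with 5′ ends 35 to 42 nt apart.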

Other observations

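Fragments just outside the two-arm loci were also compared with the sides, a comparison chosen after seeing the data. Fragments ending just before the 5p side averaged -0.83 ± 0.82 log2 against it (SD, n = 8 tables), lower in 7 of 8 (exact sign-flip p = 0.0391, adjusted p = 0.361 over 37 tests), and -0.86 ± 0.58 against the 3p side (exact sign-flip p = 0.0156, adjusted p = 0.361). Fragments starting after the 3p side averaged -0.65 ± 1.44 against it (exact sign-flip p = 0.266, adjusted p = 0.532). None passed the correction, and from 7 to 37 loci per table had such fragments.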
